A study of Saccharomyces pastorianus with 18 samples.

How the data were processed

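The series holds 18 RNA-seq libraries from 2 mutant strains of the lager yeast Saccharomyces pastorianus, a hybrid that carries an S. cerevisiae and an S. eubayanus sub-genome. Per the labels' protocols, cultures of the parents CBS1538 and W34/70 were treated with radicicol, an inhibitor of the chaperone Hsp90, at 20, 40 or 100 µg/mL, and mutants were then selected on the phenylalanine analogues B2TA (75 µg/mL) and PFPA (200 µg/mL). The mutants CBS1538 11.1 and W34/70 9.7 were grown in triplicate in 10% wort with 1 mM ZnSO4 at 13 °C, sampled on day 2 and day 4, and in a minimal medium with 0.5% ammonium sulfate, 1% dextrose and 1% maltose at 20 °C, sampled in exponential phase. Total RNA was sequenced as paired reads of 150 bp.

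The authors deposited 1 table of raw read counts per annotated feature, on a combined S. cerevisiae and S. eubayanus reference, with no normalisation. Per the submitters' processing notes, the tools were STAR, SAMtools, featureCounts and DESeq2 and the genome build was R64, which is an S. cerevisiae build. Tool versions, the S. eubayanus assembly, the handling of reads that match both sub-genomes and the use of strand in counting are not given in the sources used here. Coordinates are those of the deposited table. Reads shared between near-identical genes can be counted on either copy, so members of multi-copy families such as HXT, PAU, MAL and FLO are uncertain, and without a stated use of strand a gene and an overlapping antisense gene cannot be separated. All per-sample columns were used (0 were left out). The table has 11979 features, 6600 on the S. cerevisiae and 5379 on the S. eubayanus sub-genome, of which 9493 have a gene symbol, and 4386 symbols occur once in each sub-genome.

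Libraries were grouped by their titles into 6 groups of 3. For the CBS1538 11.1 day 2 libraries the title gives the mutant and the strain field gives the parental strain. The column names of the deposited counts mark these libraries with mt, read here as mutant, as the title does. The strain field still disagrees, and every comparison that uses these libraries carries that doubt. Other parental libraries were not analysed here. Total counts ranged from 5266324 (CBS1538 11.1 day 2 replicate 1) to 19467656 (W34/70 9.7 minimal medium replicate 1), so values near 1 CPM rested on few counts per library and carried a large counting error. No pair of replicates was a duplicate: the chi-square per degree of freedom between replicates was 17.1 or more.

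Differential expression was computed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on the counts as deposited, with TMM factors, the filterByExpr filter (minimum count 10, minimum total count 15), which kept 10894 features, and 1 fit over all 18 libraries with a mean per group. Values are given as CPM after TMM scaling, mean ± SD over n = 3 libraries. Each feature was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. There were 9 pairwise comparisons and 3 tests of whether a change differed between strains. The strains differ in gene content, so strain comparisons were also made with the counts of both copies of a gene summed. A fold against a group with 0 counts is a lower bound computed against 3 counts over the group. Intervals and such bounds cover counting error only.

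The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 5 alternatives named as later choices. The 36 gene lists (704 symbols, 9 of them absent from the table) cover amino acid, carbon, energy, stress, translation, lipid and nutrient genes, and include 3 marker lists, for sporulation and meiosis, for mating-type and haploid-specific genes, and for respiratory deficiency. Lists were tested with camera in limma 3.58.1 with its preset correlation of 0.01 and again with an estimated correlation, and with fry. Counts of members are over all features tested, with the counts adjusted over the list alone beside them. A feature counts as detected in a comparison with 10 counts or more over its libraries. Named genes are, per comparison, the 5 largest rises and 5 largest falls among called features with a symbol, a mean of at least 4 log2 CPM in the higher group and no overlap between the groups (chance alone gives no overlap for 10% of features), the 3 members with the smallest p of up to 6 lists that passed camera or had most members called one way, and a fixed set for aromatic amino acids, higher alcohols, esters and Hsp90. In strain comparisons the largest changes were also taken among S. eubayanus copies. The values of 1 named gene are not reported here, and it stays in the counts.

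The share of counts on the S. eubayanus sub-genome was compared with an exact permutation test, two-sided, which cannot give a p under 0.1 with 3 against 3 libraries. Chromosome levels are medians of log2(CPM + 0.1) over features with a mean of at least 5 CPM in the strain, for chromosomes with at least 10 such features. Allele balance is the log2 ratio of the S. cerevisiae to the S. eubayanus copy with a pseudocount of 0.5 and TMM factors per sub-genome, for genes with a mean of at least 10 counts per copy in the strain, tested with limma with a trend. The limma fit took its spread from all 18 libraries, those of the other strain included. Alternatives were DESeq2 1.42.0, DESeq2 size factors, library totals, TMM factors from S. eubayanus features only, no filter, the replicate number as a block, a fit on the compared groups only, summed copies, lists over the copies of a single sub-genome, other settings of the share and allele balance, and leaving out each library. Added after the data were seen were fits without the 2 W34/70 9.7 libraries that lack S. eubayanus chromosome VII counts, fits without the chromosomes whose level differed between replicates, an allele fit on the 9 libraries of the strain, lists on summed copies and lists with each library left out.

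The tests were tried on counts simulated from the real group means over the 10894 features, with 200 genes changed. The changed genes were drawn among those with at least 20 expected counts, so the recovered shares do not hold for weaker features. Features were drawn independently, without the shifts of whole chromosomes seen between W34/70 9.7 replicates. Each comparison was simulated a single time. For day 4 against day 2, edgeR recovered 26% of 2-fold and 88% of 4-fold changes in CBS1538 11.1 and 15% and 83% in W34/70 9.7. For minimal medium against day 2 it recovered 24% and 90% in CBS1538 11.1 and 20% and 77% in W34/70 9.7, where 5.83% of calls were false (6 of 103). The share of false calls was 7.46% (5 of 67) for the strain difference of the minimal medium against day 4 change. It was 15.4% (22 of 143) for DESeq2 in the day 4 against day 2 change of W34/70 9.7. These shares rest on few calls. For the strain difference of the day 4 against day 2 change it recovered 6% of 2-fold and 52% of 4-fold changes. Among 4026 genes simulated for the allele balance of day 4 against day 2 in W34/70 9.7, limma recovered 3% of 2-fold and 56% of 4-fold changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.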

Results

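RNA-seq read counts were obtained for 2 radicicol-derived mutants of lager yeast, CBS1538 11.1 and W34/70 9.7, in 3 conditions with 3 libraries each. Radicicol blocks the chaperone Hsp90, and the mutants had been selected on phenylalanine analogues, a selection used in brewing yeast to find cells with altered aromatic amino acid metabolism and flavour. The conditions were day 2 and day 4 of a wort fermentation at 13 °C and exponential growth at 20 °C in a minimal medium with ammonium sulfate as the nitrogen source. Library totals ranged from 5266324 to 19467656 counts. The 9 CBS1538 11.1 libraries held 5266324 to 16571345 counts and the 9 W34/70 9.7 libraries 12782267 to 19467656. For the CBS1538 11.1 day 2 libraries the labels disagree on whether the strain is the mutant or its parent, so every comparison with them below is a comparison with libraries of uncertain strain. The change from day 4 to minimal medium in CBS1538 11.1 does not compare with them, though they entered the fit that gave its spread and scaling.

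The mutants differed in the share of counts on each sub-genome. In CBS1538 11.1, 88.3% ± 0.214 (SD, n = 3) of counts lay on S. eubayanus features on day 2, 88.0% ± 0.029 on day 4 and 89.0% ± 0.364 in minimal medium. In W34/70 9.7 the share was 32.9% ± 1.67, 31.4% ± 1.43 and 32.6% ± 0.517. On day 2, under 4% of the features on S. cerevisiae chromosomes II, III, IV, VI, VIII, XII, XIII, XV and XVI reached 1 CPM in CBS1538 11.1 (1.08% of 743 features on IV, 3.88% of 464 on XIII), while W34/70 9.7 had 97.2% or more of them. CBS1538 11.1 expressed S. cerevisiae I, IX, X and XIV (88.7% to 92.6% of features), 61.4% of V, 64.2% of XI and 18.5% of VII. W34/70 9.7 expressed 48.4% of the features on S. eubayanus XI and 62.3% of those on III, where CBS1538 11.1 had 99.3% and 97.7%. Features without counts in a strain cannot be called within it. Within-strain counts over single copies are therefore not comparable between the strains. The differences in share of -55.4, -56.6 and -56.4 percentage points had a two-sided exact permutation p of 0.1, the smallest that 20 assignments of 3 against 3 libraries can give (adjusted p = 0.15 over 9 comparisons).

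The W34/70 9.7 fermentation libraries differed from each other in the RNA level of whole chromosomes. Day 2 replicate 2 and day 4 replicate 1 had 1415 and 1346 counts on 364 S. eubayanus chromosome VII features, against 283322 to 393277 in the other W34/70 9.7 libraries. Against the other replicates of their group, S. cerevisiae chromosome I stood at -0.82 (log2) in day 2 replicate 1 and -0.88 in day 4 replicate 2. S. cerevisiae XII stood at -0.85 in day 2 replicate 2 and -0.95 in day 4 replicate 1, and S. eubayanus II at 0.83 in day 2 replicate 3 and 0.78 in day 4 replicate 3. The largest such deviation was 0.09 in the minimal medium libraries of this strain and 0.30 in CBS1538 11.1. These libraries enter every W34/70 9.7 fermentation comparison below, and through the shared fit the spread used in every other comparison. Without the 2 libraries that lack S. eubayanus VII counts, CBS1538 11.1 had 2365 instead of 1749 calls for day 4 against day 2. For minimal medium against day 4 it had 3600 instead of 3074.

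**Figure D1:**
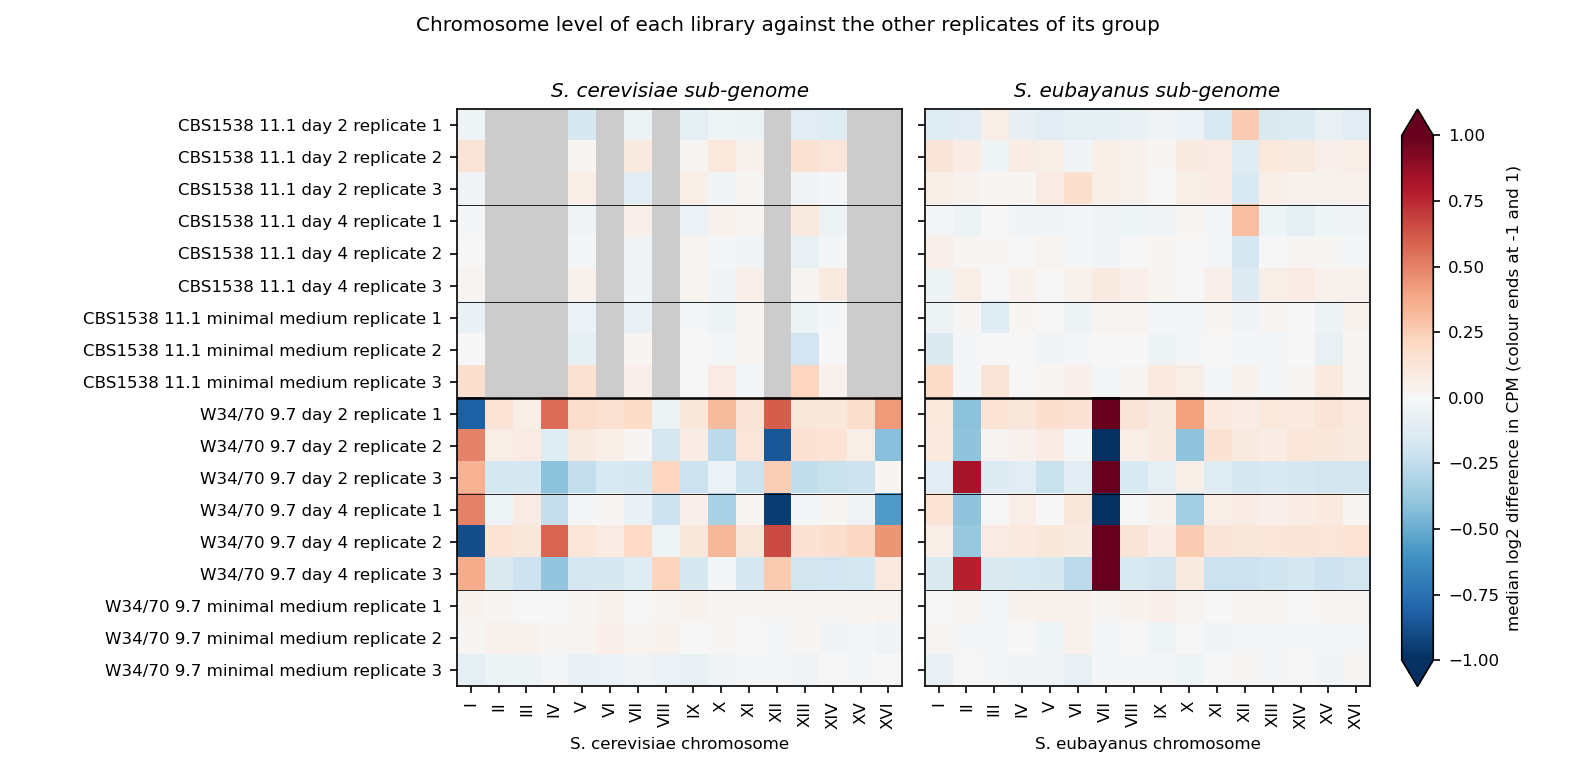
Median log2 difference in CPM of each chromosome (horizontal axis, by sub-genome) in each of the 18 libraries (vertical axis) against the other 2 replicates of its group, with grey for chromosomes with fewer than 10 features at a mean of 5 CPM in the strain. The W34/70 9.7 day 2 and day 4 libraries show blocks for S. eubayanus VII and II and S. cerevisiae I, IV, XII and XVI, and the minimal medium libraries stay within 0.09 in W34/70 9.7 and 0.22 in CBS1538 11.1.

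From day 2 to day 4 of fermentation in CBS1538 11.1, the respiratory chain, tricarboxylic acid cycle and thiamine lists had more members higher than lower, and the glycolysis and ribosomal protein lists more lower than higher. Of 36 lists 10 passed camera with its preset correlation, 10 passed fry, and 0 passed camera with an estimated correlation (2 at an unadjusted p under 0.05). COX5A, a subunit of cytochrome c oxidase (DI49_4678, S. eubayanus XIV:520910-521371), went from 61.8 ± 10.2 to 274 ± 32.7 CPM, a log2 change of 2.15 (SE 0.21, adjusted p = 0.000129). The ubiquinol-cytochrome c reductase gene QCR2 rose by 1.62 and the ATP synthase gene ATP3 by 2.06. Of the tricarboxylic acid cycle genes, the S. cerevisiae copy of citrate synthase CIT1 rose by 1.78 (SE 0.19) and that of malate dehydrogenase MDH1 by 1.52 (SE 0.24). These are the less abundant copies, and with the copies summed CIT1 rose by 0.69 and MDH1 by 0.58 (adjusted p = 0.0149 and 0.0167). ENO2, encoding enolase, dropped from 4698 ± 1264 to 1292 ± 386 CPM (log2 -1.86, SE 0.34), PGK1 changed by -1.62 and the ribosomal protein gene RPL3 by -1.92.

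As groups, 28 of 65 respiratory chain features rose and 0 fell (29 and 0 adjusted over the list alone; camera adjusted p = 4.54e-09), while 0 of 34 glycolysis and fermentation features rose and 8 fell (0 and 10 adjusted over the list alone; 1.45e-05). Of 111 ribosomal protein features 6 rose and 21 fell (6 and 23 adjusted over the list alone; 0.00103). Thiamine and vitamin B6 genes had 8 of 29 higher and 0 lower (11 and 1 adjusted over the list alone; 0.00403), and the tricarboxylic acid cycle 9 of 36 higher and 0 lower (10 and 2 adjusted over the list alone; 0.00454). Ergosterol synthesis had 15 of 52 higher and 2 lower (16 and 6 adjusted over the list alone; 0.0173). Lysine synthesis had 1 of 18 higher and 5 lower, with the same counts adjusted over the list alone (0.0111). With an estimated correlation the camera adjusted p was 0.587 for the respiratory chain, glycolysis, the tricarboxylic acid cycle and lysine, 0.63 for thiamine and 0.906 for ribosomal proteins and ergosterol. The thiamine biosynthesis gene THI4 showed the largest rise, from 36.3 ± 54.0 to 546 ± 328 CPM (log2 3.90, SE 1.03, adjusted p = 0.018), with THI20 at 2.18. The THI4 estimate was 6.68 without day 2 replicate 2, and its call ended without day 4 replicate 2 (3.50, adjusted p = 0.0555). Other large rises were the stress gene DDR2 (3.83), the peroxisomal thiolase POT1 (2.62) and the mitochondrial FMP16 (3.52, not called without day 4 replicate 1, adjusted p = 0.0607), and the largest falls were in the ribosome biogenesis genes RRP14 (-3.13) and KRI1 (-2.90 for the S. eubayanus and -2.77 for the S. cerevisiae copy), the histone chaperone gene ASF1 (-2.58) and CSR1 (-2.23).

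The labels of the day 2 libraries disagree on the strain. In total 855 features were higher and 894 lower on day 4 in CBS1538 11.1 by edgeR, 1156 of them by 2-fold or more. Instead of 1749 calls there were 1082, 1032 and 1127 without day 4 replicate 1, 2 and 3. A fit on the compared groups only called 2388 of 6628 features. With library totals in place of TMM factors, 66.6% of calls were higher instead of 48.9%.

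In W34/70 9.7 over the same interval, the respiratory chain list had more members higher than lower, and the glycolysis, trehalose and glycogen, ribosomal protein and lysine lists more lower than higher. Camera passed 14 of 36 lists with its preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05), and fry 17. The cytochrome genes QCR8 (17.3 ± 6.24 to 100 ± 11.2 CPM, log2 2.54, SE 0.32, adjusted p = 0.000159) and COX7 (2.84, SE 0.36) rose. TSL1, a subunit of the trehalose synthase complex (DI49_3992, S. eubayanus XIII:80381-83692), changed from 925 ± 61.0 to 161 ± 38.9 CPM (log2 -2.52, SE 0.29, adjusted p = 8.17e-05), and TPS1 of the same complex by -1.99. Enolase ENO2 changed by -2.40, glucokinase GLK1 by -2.11 and the homocitrate synthase gene LYS20, the entry step of lysine synthesis, by -1.93. Both copies of ILV6, the regulatory subunit of acetolactate synthase in branched-chain amino acid synthesis, were lower, by -2.51 (S. cerevisiae) and -2.34 (S. eubayanus).

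By group, 32 of 65 respiratory chain features rose and 3 fell (34 and 4 adjusted over the list alone; camera adjusted p = 4.98e-06), and 21 of 34 glycolysis and fermentation features fell with 0 higher (26 and 0 adjusted over the list alone; 7.12e-11). Trehalose and glycogen genes had 10 of 31 lower and 0 higher (11 and 0 adjusted over the list alone; 2.12e-06), ribosomal proteins 31 of 111 lower and 1 higher (the same adjusted over the list alone; 5.53e-07), and lysine synthesis 7 of 18 lower and 0 higher (8 and 0 adjusted over the list alone; 6.99e-06). Ribosome biogenesis had 25 of 107 higher and 3 lower, and the cell cycle 17 of 63 higher and 2 lower, with the same counts adjusted over the list alone (0.00748 and 0.0111). With an estimated correlation the adjusted p was 0.471 for glycolysis, 0.183 for lysine, 0.769 for ribosome biogenesis and 0.57 for the others named here. The Ehrlich pathway, which turns amino acids into higher alcohols, had 7 of 33 lower and 1 higher (the same adjusted over the list alone; 0.0153; adjusted p = 0.57 with an estimated correlation). Several large rises rested partly on single libraries: in S. cerevisiae copies, proline oxidase PUT1 stood at 11.2, 78.7 and 703 CPM in the 3 day 4 libraries and the nitrogen regulator DAL80 at 4.58, 2.61 and 60.4 CPM. Without day 4 replicate 3 their log2 changes were 3.13 instead of 5.69 and 2.68 instead of 5.31, and that of the S. eubayanus copy of the cytochrome oxidase subunit COX26 was 2.24 instead of 3.67. With summed copies DAL80 stood at 2.11 and COX26 at 1.66. The chaperone cofactor BTN2 rose by 3.52 (2.62 without day 4 replicate 2), and LSM7, which acts in mRNA decay, by 3.61 (2.13 with summed copies).

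There were 1752 features higher and 1363 lower on day 4 in W34/70 9.7 (edgeR), 1969 of them by 2-fold or more. A fit on the compared groups only gave 1006 higher and 1113 lower. Under library totals 85.3% of calls were higher instead of 56.2% and the median of all features moved from 0.08 to 0.51 on the log2 scale, with arginine synthesis and the tricarboxylic acid cycle, called lower by camera, turning to more higher than lower members (adjusted p = 0.57 for both with an estimated correlation). The count of higher features was 1159 without day 4 replicate 2 and 1163 without day 2 replicate 3.

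In CBS1538 11.1, the ergosterol and ribosome biogenesis lists had more members higher in minimal medium than on day 2, and the arginine and lysine lists more lower. Camera passed 10 of 36 lists with its preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05), and fry 19. The sterol pathway genes HMG1 (HMG-CoA reductase, 191 ± 25.9 CPM on day 2 to 2558 ± 617, log2 3.75, SE 0.32, adjusted p = 9.59e-07), ERG20 (3.05, SE 0.21) and ERG13 (3.05, SE 0.27) were higher in minimal medium. The acetaldehyde dehydrogenase gene ALD6 (DI49_5398, S. eubayanus XVI:413259-414761) went from 125 ± 45.6 to 8367 ± 938 CPM (log2 6.06, SE 0.45, adjusted p = 4.35e-07), and the proline permease gene PUT4 from 1.40 ± 0.446 to 105.4 ± 22.4 CPM (6.18, SE 0.48). The S. cerevisiae copy of the alcohol dehydrogenase gene ADH4 rose by 4.97, and both copies of cytochrome c CYC1 by 3.52 (S. eubayanus) and 3.76 (S. cerevisiae). Arginine genes were lower, with ARG7 at -3.75 and ARG4 at -2.72, as was the tryptophan and tyrosine permease gene TAT2 (445 ± 103 to 15.7 ± 0.361 CPM, -4.83, SE 0.51).

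The ergosterol list had 24 of 52 features higher and 2 lower (24 and 3 adjusted over the list alone; camera adjusted p = 3.84e-08), ribosome biogenesis 46 of 107 higher and 1 lower (48 and 1 adjusted over the list alone; 8.32e-07), and the respiratory chain 26 of 65 higher and 2 lower (27 and 3 adjusted over the list alone; 5.35e-06). Purine synthesis had 9 of 27 higher and 1 lower, arginine synthesis 0 of 17 higher and 9 lower, trehalose and glycogen 0 of 31 higher and 14 lower, and lysine 1 of 18 higher and 7 lower, all with the same counts adjusted over the list alone (0.00948, 5.14e-05, 0.00118 and 0.0019). Maltose genes, a multi-copy family, had 0 of 11 higher and 5 lower (0 and 6 adjusted over the list alone; 0.0276). With an estimated correlation the adjusted p was 0.461 for ergosterol, 0.4 for arginine and lysine and 0.753 for the others. Examples were GSY2, glycogen synthase (-2.52), and LYS21 (-3.00). THI4 was lower at -6.08 (SE 1.24), or -3.29 without day 2 replicate 2, and the heat-induced membrane protein gene YRO2 at -5.82. The S. cerevisiae copy of PAU2, of the near-identical PAU family and so uncertain, stood at 23.4 ± 4.64 against 0.749 ± 0.788 CPM. The doubt about the strain of the day 2 libraries applies here too. By edgeR 1490 features were higher and 1678 lower, 2357 by 2-fold or more, and under library totals 58.0% of calls were higher instead of 47.0%.

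The ribosome biogenesis and cell cycle lists of W34/70 9.7 were mostly higher in minimal medium than on day 2, and the trehalose and glycogen, glycolysis and hypoxic lists mostly lower. Camera passed 19 of 36 lists with its preset correlation and 0 with an estimated one (7 at an unadjusted p under 0.05), and fry 30. The histone genes HTA2 (15.3 ± 1.40 to 658 ± 64.04 CPM, log2 5.42, SE 0.39, adjusted p = 6.69e-08), HHF2 (5.38) and HTB2 (3.68), the inositol transporter ITR1 (4.91) and the S. cerevisiae copy of the zinc transporter ZRT1 (95.4 ± 88.1 to 5124 ± 489 CPM, 5.75, SE 0.66, or 6.84 without day 2 replicate 2) rose. With summed copies the values were 3.24 for HTA2, 3.55 for HHF2, 2.19 for HTB2 and 2.71 for ITR1. Phosphoglucomutase PGM2 (DI49_4193, S. eubayanus XIII:468237-469946) changed from 2478 ± 254 to 22.1 ± 7.26 CPM (-6.81, SE 0.33, adjusted p = 2.17e-09), glucokinase GLK1 from 2386 ± 523 to 17.7 ± 3.43 (-7.07, SE 0.33), hexokinase HXK1 from 20050 ± 7310 to 231 ± 97.0 (-6.44, SE 0.49) and glycogen synthase GSY2 from 5258 ± 703 to 34.3 ± 15.2 (-7.26, SE 0.44). Among S. cerevisiae copies, the stress gene HSP30 changed from 1720 ± 679 to 1.31 ± 0.229 CPM (-10.35, SE 1.44), the hypoxic translation factor ANB1 from 484 ± 126 to 2.503 ± 1.01 (-7.60, SE 0.51), TDH1 by -7.93 and the amino acid permease BAP3 by -8.83.

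All 31 trehalose and glycogen features were lower (31 adjusted over the list alone; camera adjusted p = 4.06e-17). Ribosome biogenesis had 92 of 107 higher and 0 lower (94 and 0 adjusted over the list alone; 1.69e-18), the cell cycle 50 of 63 higher and 2 lower, and the respiratory chain 50 of 65 higher and 4 lower (the same adjusted over the list alone; 5.53e-10 and 4.11e-09). Glycolysis and fermentation had 25 of 34 lower and 1 higher (26 and 1 adjusted over the list alone; 5.26e-08), hypoxic genes 21 of 33 lower and 1 higher (24 and 1 adjusted over the list alone; 1.34e-06) and gluconeogenesis 19 of 25 lower and 0 higher (20 and 0 adjusted over the list alone; 1.34e-06). With an estimated correlation the adjusted p was 0.166 for trehalose and glycogen and for hypoxic genes, 0.204 for ribosome biogenesis, 0.0727 for the cell cycle, 0.215 for the respiratory chain and glycolysis and 0.0995 for gluconeogenesis. The heat-shock list was not called, with 18 of 55 higher and 16 lower (the same adjusted over the list alone; 0.936). Within the respiratory list CYC1 (3.85) and COX8 (3.65) rose while the S. cerevisiae copy of COX5B, the hypoxic isoform of its subunit, was at -4.45. The annotated S. eubayanus feature of the hexose transporter HXT3, a multi-copy family member, stood at 0.244 ± 0.184 against 76.4 ± 45.8 CPM, whereas the 2 copies summed gave a log2 change of 1.65, so its direction is uncertain. RGI2 had 3 counts in minimal medium against 663 on day 2. In all, 3138 features were higher and 2944 lower (edgeR; 55.8% of features tested), 4720 by 2-fold or more. Under library totals 66.2% of calls were higher instead of 51.6%, and the median of all features moved from 0.04 to 0.42.

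**Figure D2:**
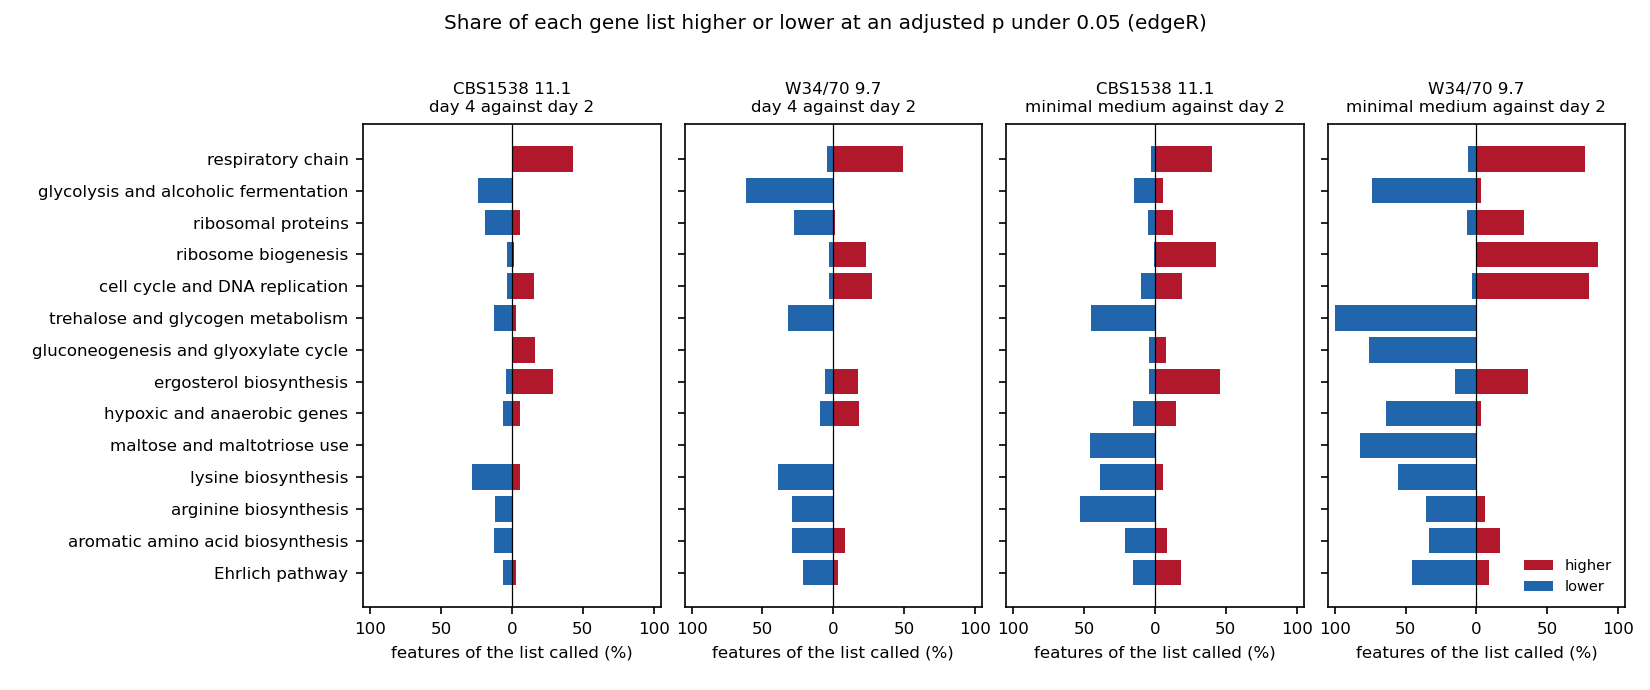
Share of the features of 14 gene lists (vertical axis) called higher (red, to the right) or lower (blue, to the left) by edgeR at an adjusted p under 0.05, in percent of the features tested, for 4 within-strain comparisons with 3 libraries per group. Trehalose and glycogen genes reach 31 of 31 lower in W34/70 9.7 in minimal medium against 14 of 31 in CBS1538 11.1, where S. cerevisiae copies without counts cannot be called (16 and 12 of 16 with the copies summed). The arginine direction from day 2 to day 4 in W34/70 9.7 turns under library totals.

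Set against day 4, more ribosome biogenesis members were higher than lower in minimal medium in each strain. The day 2 libraries of uncertain strain are not compared here but entered the shared fit. Camera passed 16 of 36 lists in CBS1538 11.1 and 18 in W34/70 9.7 with its preset correlation and 0 in each with an estimated one (2 and 9 at an unadjusted p under 0.05), and fry 22 and 27. In CBS1538 11.1, 46 of 107 ribosome biogenesis features were higher and 1 lower (48 and 1 adjusted over the list alone; camera adjusted p = 5.75e-09), 36 of 111 ribosomal protein features higher and 2 lower (40 and 2 adjusted over the list alone; 7.93e-06), and 21 of 52 ergosterol features higher and 1 lower (24 and 1 adjusted over the list alone; 7.93e-06), with adjusted p values of 0.433, 0.595 and 0.406 with an estimated correlation. In W34/70 9.7, 89 of 107 ribosome biogenesis features were higher and 0 lower (94 and 0 adjusted over the list alone; 1.38e-20), 29 of 31 trehalose and glycogen features lower and 0 higher (30 and 0 adjusted over the list alone; 2.59e-16), and 24 of 33 hypoxic features lower and 1 higher (7.76e-09), with adjusted p values of 0.145, 0.145 and 0.0622 with an estimated correlation. There were 1463 features higher and 1611 lower in CBS1538 11.1 and 2199 higher and 2501 lower in W34/70 9.7. In a fit on the compared groups only, 4148 of 6677 features were called in CBS1538 11.1 (2118 higher and 2030 lower). In W34/70 9.7 that fit called 5575 of 10562 features (2659 higher and 2916 lower). The strains' counts, those of list members included, are not comparable, because CBS1538 11.1 expressed few features of most S. cerevisiae chromosomes.

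Between the strains, the missing S. cerevisiae chromosomes dominated the single-copy comparison. On day 2, where the labels of the CBS1538 11.1 libraries disagree, the S. cerevisiae copies of HXK1, PGM2, the maltase gene MAL12 (a multi-copy family, uncertain), PRC1 and the elongation factor YEF3 had 0 counts in CBS1538 11.1 and were at least 37140-, 35430-, 30680-, 26110- and 23980-fold higher in W34/70 9.7. The S. eubayanus copies of the vacuolar peptidase APE1, MYO3, SCW10, the zinc transporter ZRT3 and CPR4 had 0 counts in W34/70 9.7 and were at least 6466-, 5303-, 5241-, 3419- and 3292-fold lower. On day 4 the bounds were led by S. cerevisiae HOR7 (at least 70650-fold higher) and S. eubayanus UBA1 (at least 7121-fold lower), and in minimal medium by S. cerevisiae RPS31 (at least 47950-fold higher) and S. eubayanus FUM1 (at least 5977-fold lower). Among S. eubayanus copies with 0 counts in CBS1538 11.1, PDA1, a subunit of pyruvate dehydrogenase, was at least 3694-fold higher in W34/70 9.7 on day 4 (with the copies summed it was lower, at -1.85) and ECM1 at least 1512-fold higher in minimal medium. The 14-3-3 gene BMH1 had 20159 counts in W34/70 9.7 and 3 in CBS1538 11.1 on day 2, and its summed copies were not called (-0.11). With summed copies HXK1, PRC1, YEF3 and CPR4 on day 2, HOR7 on day 4 and RPS31 in minimal medium were not called between strains (-0.16, 0.67, 0.24, -0.22, 0.18 and 0.71). By edgeR 5827 features were higher and 2553 lower in W34/70 9.7 on day 2, 5980 and 2696 on day 4, and 5972 and 2599 in minimal medium. With TMM factors from S. eubayanus features only, 84.4%, 82.7% and 81.3% of calls were higher, and under library totals on day 2 57.4% instead of 69.5%. These scalings placed the median of all features at 1.93, 2.06 and 2.04, or at 0.53, 0.88 and 0.80, against 1.22, 1.33 and 1.31 with TMM.

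With the copies of each gene summed (4369 genes), W34/70 9.7 still differed from CBS1538 11.1 in 1124 genes higher and 1102 lower on day 2, 1398 and 1271 on day 4, and 1493 and 1271 in minimal medium. In minimal medium the trehalose and glycogen gene PGM2 was at -4.72 (SE 0.29, adjusted p = 1.69e-10), the branching enzyme GLC3 at -5.05 (SE 0.35), the hypoxic fumarate reductase FRD1 at -4.03 (SE 0.28), the membrane sensor MGA2 at -2.56 (SE 0.17) and the zinc-regulated IZH4 at -7.33 (SE 0.25, adjusted p = 4.76e-14). Trehalose and glycogen had 16 of 16 genes lower (16 adjusted over the list alone; camera adjusted p = 1.24e-12; adjusted p = 0.202 with an estimated correlation), ergosterol 21 of 26 lower and 0 higher (21 and 1 adjusted over the list alone; 7.93e-08; adjusted p = 0.265 with an estimated correlation) and ester synthesis 7 of 7 lower (7 adjusted over the list alone; 1.25e-04; adjusted p = 0.139 with an estimated correlation). Hypoxic genes had 10 of 12 lower and 1 higher (the same adjusted over the list alone; 1.14e-07) and passed with an estimated correlation (adjusted p = 0.00241). On day 2 the oxidative stress list had 11 of 18 higher and 0 lower (0.000986; adjusted p = 0.259 with an estimated correlation), and on day 4 the tricarboxylic acid cycle had 14 of 18 lower and 0 higher (0.00278; adjusted p = 0.628 with an estimated correlation). With the copies kept apart 0 lists passed camera in any condition (0, 0 and 5 of 36 at an unadjusted p under 0.05), and fry called 36, 36 and 29.

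The tests of whether a change differed between strains gave 84 features higher and 84 lower for day 4 against day 2, 734 and 899 for minimal medium against day 2 and 508 and 628 for minimal medium against day 4 (edgeR, W34/70 9.7 minus CBS1538 11.1). The tests against day 2 compare with the CBS1538 11.1 libraries whose labels disagree. The test against day 4 does not, though these libraries entered the shared fit. Fitted on the compared groups only, it gave 526 higher and 905 lower. The count for day 4 against day 2 was unstable: it was 753 with DESeq2, 791 with summed copies, 27 without CBS1538 11.1 day 4 replicate 2 and 0 when fitted on its 4 groups alone. It was also lower without CBS1538 11.1 day 4 replicate 1 (37) or W34/70 9.7 day 2 replicate 1 (52), day 2 replicate 3 (95), day 4 replicate 1 (75) or day 4 replicate 2 (28), and higher, at 272, without W34/70 9.7 day 2 replicate 2 and 313 without CBS1538 11.1 day 2 replicate 3. For minimal medium against day 2 the 734 higher features became 427, 432 and 441 without W34/70 9.7 minimal medium replicate 3, replicate 1 and CBS1538 11.1 minimal medium replicate 3. For minimal medium against day 4 the 508 became 272 and 292 without W34/70 9.7 minimal medium replicates 1 and 3, 323 without its day 4 replicate 2, and 336, 305 and 314 without CBS1538 11.1 day 4 replicates 1, 2 and 3. In minimal medium against day 2, ALD6 was higher by 6.06 in CBS1538 11.1 and changed by -0.14 in W34/70 9.7 (difference -6.20, SE 0.56, adjusted p = 3.12e-06), and HMG1 by 3.75 against -0.58 (difference -4.33, SE 0.42), while GLK1, HXK1 and PGM2 were lower in W34/70 9.7 by differences of -6.35, -4.40 and -6.08. With summed copies the trehalose and glycogen list had 15 of 16 genes with a lower change in W34/70 9.7 and 0 higher (6.52e-18; adjusted p = 0.0835 with an estimated correlation) and the hypoxic list 9 of 12 lower and 0 higher, which passed with an estimated correlation (adjusted p = 0.000481, or 0.0655 with the copies kept apart). Across 5182 S. eubayanus features, which are not independent replicates, the changes of the strains had a Pearson r of 0.522 for day 4 against day 2 and 0.557 for minimal medium against day 2. For day 4 against day 2, 291 features were higher in both strains (99.1 if the calls were independent), 391 lower in both (111 if independent), and 17 called in opposite directions.

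**Figure D3:**
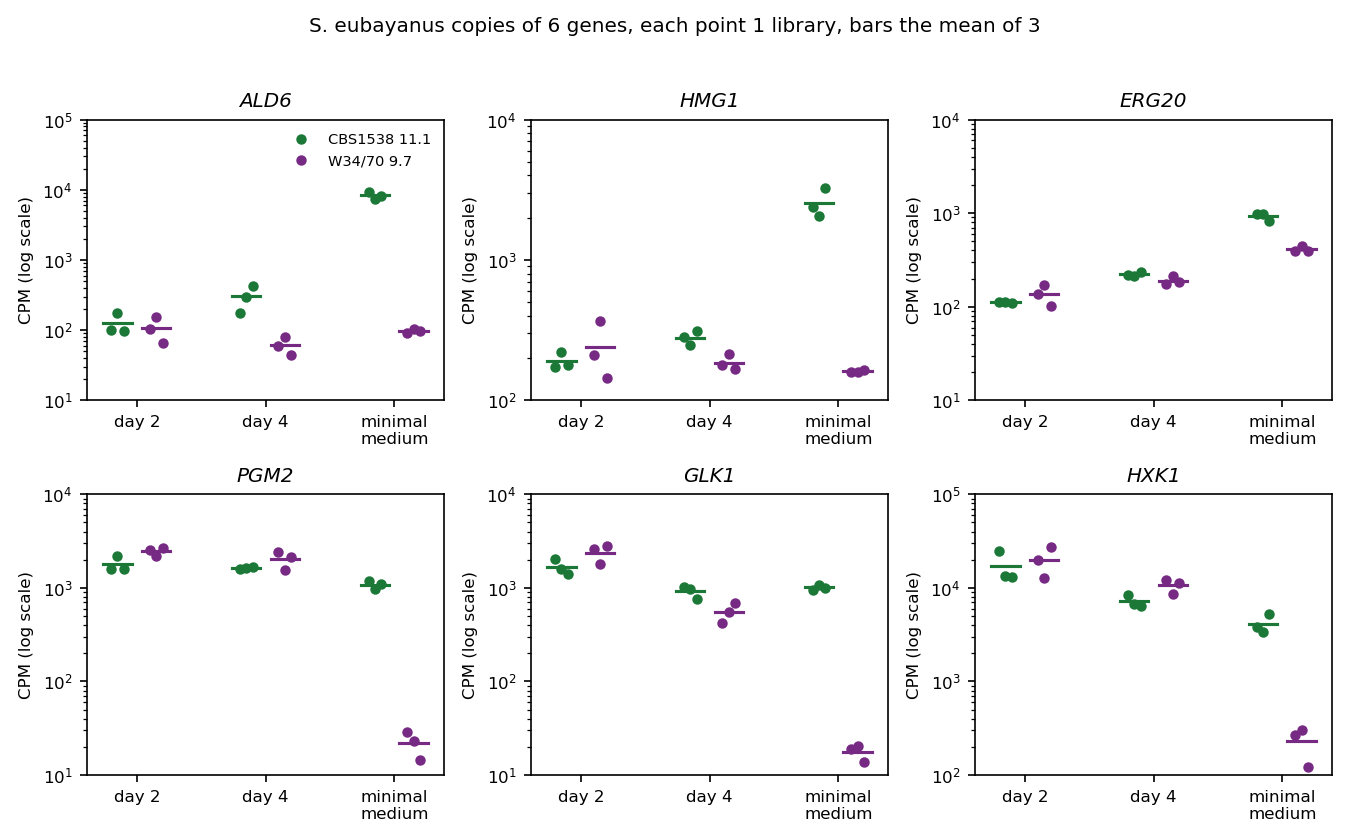
CPM on a log axis of the S. eubayanus copies of 6 genes on day 2, day 4 and in minimal medium, each point 1 library and each bar the mean of 3, for CBS1538 11.1 (green) and W34/70 9.7 (purple). ALD6, HMG1 and ERG20 rise most in CBS1538 11.1 in minimal medium (ALD6 to 8367 CPM), and PGM2, GLK1 and HXK1 drop in W34/70 9.7 (PGM2 to 22.1 CPM).

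The genes of aromatic amino acid, higher alcohol and ester metabolism and of Hsp90 were a fixed set. The S. eubayanus copy of ARO4, the tyrosine-inhibited DAHP synthase at the entry of the aromatic pathway, was lower on day 4 than on day 2 in CBS1538 11.1 (1426 ± 273 to 790 ± 10.4 CPM, log2 -0.85, SE 0.24, adjusted p = 0.0234, lost without day 2 replicate 1 at -0.70 and without any of the day 4 libraries at -0.86 to -0.87) and in W34/70 9.7 (-1.24, SE 0.24, adjusted p = 0.0019, or -0.79 with library totals). In minimal medium this copy was lower than on day 2, at -1.40 and -1.45. The S. cerevisiae copy of ARO4 in W34/70 9.7 was not called, at -1.23 on day 4 (adjusted p = 0.0646) and -0.75 in minimal medium (0.189). Chorismate mutase ARO7, which commits chorismate to phenylalanine and tyrosine, rose in W34/70 9.7 from day 2 to day 4 by 2.00 (S. eubayanus, SE 0.27) and 1.90 (S. cerevisiae, SE 0.31), and was higher in minimal medium by 2.73 and 3.27. The change of its S. eubayanus copy differed between strains by 2.00 for both steps. TYR1 (-1.42) and HSP82 (-1.45, SE 0.27, adjusted p = 0.000626) were lower in minimal medium in CBS1538 11.1. In W34/70 9.7, the transaminase BAT2 was lower (-3.02 and -1.72 for the S. eubayanus and S. cerevisiae copies, -2.78 summed), as were HSP82 (S. eubayanus copy, -1.03, not called with summed copies) and the S. cerevisiae copy of the alcohol acetyltransferase ATF1, which makes acetate esters (89.5 ± 12.1 to 11.8 ± 0.107 CPM, -2.92, SE 0.19). The S. eubayanus copy of ARO10 of the Ehrlich pathway was at 0.67 in CBS1538 11.1 (adjusted p = 0.236) and 0.89 in W34/70 9.7 (0.0707) from day 2 to day 4. It was called in W34/70 9.7 with summed copies (1.045), DESeq2 (0.89), library totals (1.33), without the 2 libraries that lack S. eubayanus VII counts (1.00), and without day 2 replicate 1 (1.29) or day 4 replicate 1 (1.21), and in CBS1538 11.1 in a fit on the compared groups only (0.66). The S. cerevisiae copy of ARO10 in W34/70 9.7 was at 1.31 (adjusted p = 0.253), 2.65 and called without day 2 replicate 1, and 0.29 and not called without day 4 replicate 2. Neither HSP82 nor HSC82 was called in that interval in either strain, except HSC82 in W34/70 9.7 in a fit on the compared groups only (-0.70). As a group, the Ehrlich list had 15 of 33 lower and 3 higher in minimal medium in W34/70 9.7 (the same adjusted over the list alone; camera adjusted p = 0.00662; adjusted p = 0.388 with an estimated correlation). The aromatic list had 0 of 24 higher and 3 lower on day 4 in CBS1538 11.1 (0 and 0 adjusted over the list alone; camera adjusted p = 0.747) and 2 higher and 7 lower in W34/70 9.7 (2 and 8 adjusted over the list alone; 0.0606). Between strains with summed copies, ATF2 was lower in W34/70 9.7 by -2.29, -2.42 and -2.16 on day 2, on day 4 and in minimal medium, HSP82 by -1.50 and -1.22 on day 2 and day 4, and ARO7 was higher by 1.56 and 1.94 on day 4 and in minimal medium.

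The marker lists for other cell states were mostly not called. The sporulation and meiosis list (36 features) had 1 higher and 0 lower on day 4 in CBS1538 11.1 (0 and 0 adjusted over the list alone; 0.476) and 6 higher and 0 lower in W34/70 9.7 (3 and 0 adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.57 with an estimated correlation). The mating-type and haploid-specific list had 1 and 4 higher with 0 lower in CBS1538 11.1 and W34/70 9.7 (0 and 3 adjusted over the list alone; 0.747 and 0.108). The respiratory-deficiency list had 3 higher and 0 lower in CBS1538 11.1 (3 and 1 adjusted over the list alone; 0.254) and 2 higher and 3 lower in W34/70 9.7 (0.318). Under library totals the respiratory-deficiency list turned to 5 higher and 2 lower on day 4 in W34/70 9.7. In minimal medium against day 2 the camera adjusted p of the marker lists, in the order above, was 0.962, 0.429 and 0.262 in CBS1538 11.1 and 0.183, 0.141 and 0.1 in W34/70 9.7.

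The copies of a gene mostly moved together. Across genes with both copies, which are not independent replicates, the changes of the S. cerevisiae and S. eubayanus copies had a Pearson r of 0.602 (day 4 against day 2) and 0.628 (minimal medium against day 2) in CBS1538 11.1 and 0.737 and 0.792 in W34/70 9.7. Where both copies were called in W34/70 9.7, 561 of 570 and 1525 of 1584 had the same direction. The balance between copies changed (limma) for 134 of 1061 genes from day 2 to day 4 in CBS1538 11.1, 71 toward the S. cerevisiae and 63 toward the S. eubayanus copy, and for 297 in minimal medium (188 and 109). The CBS1538 11.1 counts use the day 2 libraries whose labels disagree. In W34/70 9.7 it changed for 17 of 4036 genes from day 2 to day 4 (13 and 4) and for 456 in minimal medium (285 and 171). These fits took their spread from all 18 libraries, including CBS1538 11.1 libraries in which most S. cerevisiae copies had few counts. A fit on the 9 libraries of the strain gave 266 and 1130 for W34/70 9.7, so the counts of 17 and 456 depend on that choice. Of 339 genes whose S. eubayanus copy lies on VII, 0 were called in W34/70 9.7 for day 4 or for minimal medium against day 2. Single libraries moved these counts: 134 became 45 without CBS1538 11.1 day 4 replicate 3 and 236 without day 2 replicate 2, 17 became 0 without W34/70 9.7 day 2 replicate 3, day 4 replicate 2 or day 4 replicate 3, 1 without day 4 replicate 1, 2 without day 2 replicate 1 and 28 without day 2 replicate 2, and 456 became 200 without W34/70 9.7 minimal medium replicate 1.

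**Figure D4:**
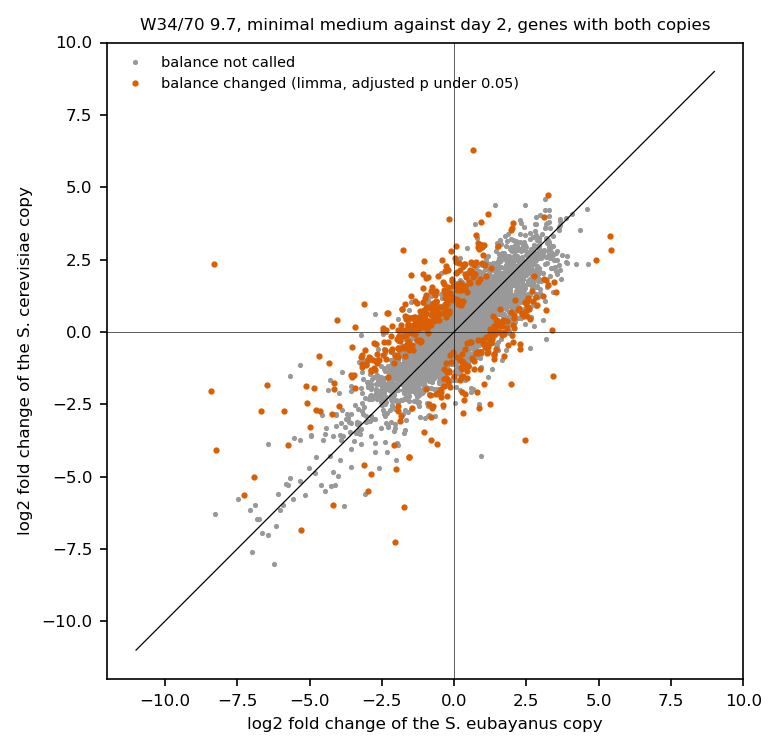
Log2 fold change from day 2 to minimal medium in W34/70 9.7 of the S. eubayanus copy (horizontal axis) and the S. cerevisiae copy (vertical axis) of 4036 genes, each point 1 gene, with the line of equal change. The 456 genes whose balance was called as changed in the fit on all 18 libraries (orange, limma) lie off the line. The other genes (grey) were not called, which does not place them on the line, and a fit on the 9 libraries of the strain called more. The Pearson r was 0.792 across genes.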

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

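The tests of the missing chromosome VII counts, of the summed copies and of the strain-dependent response to the minimal medium condition were chosen after the results were seen. So were the counts over other splits of the libraries.

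S. eubayanus chromosome VII was close to absent in 2 of the W34/70 9.7 fermentation libraries, day 2 replicate 2 and day 4 replicate 1. Their depth was not low, with a ratio of median totals of 1.104 to the 4 other fermentation libraries. The S. cerevisiae copies of its genes rose by at most 0.093 on the log2 scale, where a transfer of the missing reads would give 0.473 and 0.432, and 98.04% of 408 S. cerevisiae chromosome II features reached 1 CPM, against at most 7.353% in a CBS1538 11.1 library, which excludes a swap with that strain. Of 4 parts of the chromosome none kept more than 0.8515% of its share. A hypothesis is that the whole chromosome, or at least the stretch examined, was lost in these cultures, which may be tested by sequencing their DNA.

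The CBS1538 11.1 day 2 libraries carry labels that disagree on whether the strain is the mutant or its parent. The chromosome median of the day 2 to day 4 change that lay farthest from the median of all detected features was -0.347, on S. eubayanus III, under the bound of 0.5 set for a difference of chromosome content. The value was -0.477 (S. eubayanus I) in W34/70 9.7, where the labels do not disagree. No chromosome reached that bound. A median under it cannot exclude smaller differences in copy number, so another chromosome content is not excluded. The titles and the column names of the deposited counts give the mutant, and the strain field alone gives the parent. From the counts, a parental strain with the same chromosomes also remains open.

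Hypoxic and anaerobic genes were lower in W34/70 9.7 than in CBS1538 11.1 in minimal medium. With the copies summed the median was -3.534, so missing S. cerevisiae copies in CBS1538 11.1 do not account for it, and over 4 scalings the median closest to 0 was -2.062. With summed copies the difference of the change from day 2 had an adjusted p of 0.000481 by camera with an estimated correlation, and with the copies kept apart it did not pass (0.0655). A hypothesis is that the response to the minimal medium condition depends on the strain. That condition differed from day 2 in medium, temperature and growth phase together, so a response to the medium alone cannot be told apart. The oxygen supply of the cultures was not measured here, and a difference in it may give the same pattern.

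The following genes had a change that differed between the strains by a test of the difference itself (edgeR, W34/70 9.7 minus CBS1538 11.1, log2, n = 3 per group), with the labels of the CBS1538 11.1 day 2 libraries in doubt. For day 4 against day 2 the differences were -2.85 for POT1, 3.38 for ASF1, -1.75 for COX5A, -1.39 for QCR2, -1.43 for THI6, -2.28 for MDH2, -1.92 for PRB1 and 2.00 for ARO7 among S. eubayanus copies. Among S. cerevisiae copies they were -1.07 for CIT1, -1.43 for MDH1 and 8.29 for BTN2, the last resting on CBS1538 11.1 levels of 0 to 2.0 CPM. The S. cerevisiae copy of BTN2 lies on chromosome VII, of which 18.5% of 524 features reached 1 CPM in CBS1538 11.1 on day 2. Whether that strain carries the copy is uncertain. With the copies summed CIT1 (-0.48, adjusted p = 0.287) and MDH1 (-0.54, 0.16) did not differ by the test, and BTN2 was at 3.98 (adjusted p = 0.00217). These were 11 of 76 named features, against 1.542% of all features tested. Most named features were chosen from these data for their change within a strain, which favours a difference between strains. In a fit on the compared groups only, this test had 0 calls.

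For minimal medium against day 2, 41 of 78 named features differed, against 14.99% of all features tested, with named features chosen in the same way. Among S. eubayanus copies, metabolic, transport and sterol genes had differences of -3.47 (PUT4), -6.20 (ALD6), -5.97 (COX26), 8.10 (THI4), -1.46 (ERG20), -4.33 (HMG1), -2.15 (ERG13), 1.59 (ARG4), 1.45 (LYS21), 1.12 (LYS1), 1.25 (TYR1), 2.00 (ARO7), 1.27 (ARO3), 2.44 (ITR1) and 1.56 (COX8). Storage, glycolytic and stress genes had -2.93 (GDB1), -4.74 (GSY2), -6.08 (PGM2), -5.15 (GPH1), -6.35 (GLK1), -4.40 (HXK1), -8.00 (RGI2) and -6.38 (DDR2), and the hexose transporter HXT3, a multi-copy family member, -8.35. Histone and ribosome biogenesis genes had 2.31 (HTA2), 1.90 (HHF2), 1.35 (HTB2), 2.19 (UTP4) and 1.55 (IMP4). The S. cerevisiae copies had -8.59 (PAU2, a near-identical family), -2.93 (ADH4), 1.58 (LYS1), -1.81 (BAT2), 2.47 (ZRT1), -10.38 (HSP30), -3.72 (COX5B), -6.33 (TDH1), -6.62 (TIR1), -8.57 (ANB1) and -2.48 (MGA2). Some of these rest on levels near 0 in 1 strain: THI4 (0 to 0.354 CPM), PAU2 (0 to 2.19) and COX26 (0.631 to 4.93) in W34/70 9.7, and HSP30 (0 to 3.33) and DDR2 (0 to 1.98) in CBS1538 11.1. The S. cerevisiae copy of HSP30 lies on chromosome III, of which 2% of 150 features reached 1 CPM in CBS1538 11.1 on day 2. That strain may lack the copy, so its value may reflect gene content, not a response. THI4 also rests on CBS1538 11.1 day 2 replicate 2, at 98.6 CPM against 2.57 and 7.71, without which its change in CBS1538 11.1 was -3.29 instead of -6.08. With the copies summed the test no longer called HTA2 (0.17), HHF2 (0.41), HTB2 (-0.09), ITR1 (0.28), IMP4 (0.83) or ARO3 (-0.54), with adjusted p values of 0.781, 0.451, 0.862, 0.45, 0.0962 and 0.158. HXT3 turned to 2.25, and values moved to 4.335 for THI4, -2.84 for DDR2, 2.46 for LYS21 and 1.79 for the copies of LYS1.

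Other splits of the same libraries were counted for each set of calls. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split was the 1 with the most calls in each case, with the highest other split after it: for day 4 against day 2, 1749 and 0 in CBS1538 11.1 and 3115 and 84 in W34/70 9.7; for minimal medium against day 2, 3168 and 8, and 6082 and 0; for minimal medium against day 4, 3074 and 0, and 4700 and 0. Between strains they were 8380 and 0 on day 2, 8676 and 0 on day 4, and 8571 and 0 in minimal medium. For allele balance they were 134 and 1, and 17 and 3, from day 2 to day 4, and 297 and 6, and 456 and 0, from day 2 to minimal medium, CBS1538 11.1 first.

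For the strain differences of a change, 100 splits were compared, the real one included. As many calls came in 11 of 100 splits for day 4 against day 2 (168 real, 814 highest other) and in 6 of 100 for minimal medium against day 2 (1633 and 4373), so over all splits chance is not excluded for these counts. For minimal medium against day 4 it was 2 of 100 (1136 and 3756), a share under 0.05, and 7.46% of calls were false for this test on simulated counts. No conclusion on chance is drawn from this share, for the reason given next. The splits with several times the real count point to a structure of the samples: of the 10, 5 and 1 other splits with as many calls, 9, 5 and 1 opposed the strains' condition labels to each other, so that the change shared by the strains entered the difference, and such splits are a poor measure of chance. Of the splits that did not oppose the labels, 1, 0 and 0 had as many calls, with highest counts of 350, 1318 and 343.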

How the results depend on the processing

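The fits without the 2 W34/70 9.7 libraries that lack S. eubayanus VII counts, the fits without the chromosomes that differ between replicates, the allele fit on 9 libraries, the lists on summed copies and the lists with 1 library left out are tests chosen after the data were seen. Of 395 named values, 393 kept their side of the threshold, and their direction where called, with DESeq2 size factors. This number was 387 with DESeq2, 377 with library totals, 392 without a filter, 383 with TMM factors from S. eubayanus features only and 391 with the replicate number as a block. With the copies summed, where some named features have no value, 246 kept both, 18 gained the call, 60 lost it and 29 reversed. Over all conditions the replicate numbers did not pair libraries. Of 18 same-numbered pairs 4 had a correlation above 0.1, and 7 of 18 libraries correlated best with their own number. Between day 2 and day 4 in CBS1538 11.1, same-numbered pairs correlated at 0.218, 0.061 and 0.17, and other pairs at -0.2 to 0.071. This leaves open whether the number marks shared cultures in that strain. In W34/70 9.7, day 2 replicates 1, 2 and 3 correlated best with day 4 replicates 2, 1 and 3 (0.862, 0.948 and 0.813), a hint from the data, not the design, that both days sampled the same cultures. Apart from the fits with the replicate number as a block, day 2 and day 4 libraries were treated as unpaired in every test and split. No fit with the crossed W34/70 9.7 pairs was made. Where a value below differs from the report the cause was not tested, except that summed copies test fewer features. Depth limits features near 1 CPM, most in CBS1538 11.1 day 2 replicate 1.

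The strain difference of the day 4 against day 2 change had 61 calls with library totals, 64 with the block, 791 with summed copies, 753 with DESeq2, 0 in a fit on the compared groups only (edgeR; 1791 features at an unadjusted p under 0.05 in the fit on all libraries), 273 without the 2 W34/70 9.7 libraries and 349 without the variable chromosomes. Leaving out 1 library gave 27 (CBS1538 11.1 day 4 replicate 2) to 313 (CBS1538 11.1 day 2 replicate 3). For day 4 against day 2 in CBS1538 11.1 that range was 1032 (day 4 replicate 2) to 1761 (day 2 replicate 3). With summed copies W34/70 9.7 had 2032 calls for day 4 against day 2, 2983 for minimal medium against day 2 and 2503 for minimal medium against day 4, and the strains differed in 2226, 2669 and 2764 genes on day 2, on day 4 and in minimal medium.

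With summed copies 8 lists passed camera for day 4 against day 2 and 10 for minimal medium against day 2 in W34/70 9.7, 11 for the strain difference of the day 4 change, and 7, 9 and 16 between strains. With an estimated correlation and the copies kept apart, 0 passed in each of the 6 within-strain comparisons (2 to 9 at an unadjusted p under 0.05; fry 10 to 30), and 0, 0 and 1 for the strain differences of the day 4, minimal medium against day 2 and minimal medium against day 4 changes. With the copies summed as well, 1 passed for minimal medium against day 4 in W34/70 9.7 and 1 for each strain difference of a minimal medium change. With S. cerevisiae copies only, 1 list passed for day 4 against day 2 in CBS1538 11.1 and 6 in W34/70 9.7, 0 for each minimal medium comparison in CBS1538 11.1, 0, 4 and 5 for the strain differences of a change, and 22, 18 and 13 between strains. With S. eubayanus copies only, 8 passed for day 4 against day 2 and 10 for minimal medium against day 4 in W34/70 9.7, 17 for the strain difference of the day 4 change, and 28, 31 and 29 between strains. Leaving out 1 library gave 2 (CBS1538 11.1 day 2 replicate 3) to 10 lists (W34/70 9.7 day 2 replicate 2) for that difference and 8 (day 2 replicate 3) to 17 (day 2 replicate 2) for day 4 against day 2 in W34/70 9.7.

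Over genes with both copies the S. eubayanus share was 90.64%, 90.31% and 90.63% in CBS1538 11.1 and 34.9%, 33.13% and 34.34% in W34/70 9.7 on day 2, on day 4 and in minimal medium. Without the 100 features with the most counts it was 89.23%, 88.7% and 89.47% in CBS1538 11.1, and 29.53% on day 4 and 30.86% in minimal medium in W34/70 9.7. For allele balance in W34/70 9.7, day 4 against day 2 had 9 calls with the block, 266 in the fit on 9 libraries, 0 without the 2 libraries (limma; 439 genes at an unadjusted p under 0.05 with them), and 0 (day 2 replicate 3, day 4 replicate 2 or day 4 replicate 3) to 28 (day 2 replicate 2) with 1 library left out. Minimal medium against day 2 had 1130 in the fit on 9 libraries and 200 (minimal medium replicate 1) to 309 (day 2 replicate 2) with 1 library left out. In CBS1538 11.1 day 4 against day 2 had 45 (day 4 replicate 3) to 236 (day 2 replicate 2).

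Values reversed by summing copies were 1.65 for HXT3 (minimal medium against day 2, W34/70 9.7) and these between strains. On day 2 they were -0.67 (TMT1), -1.585 (DNF1), -0.76 (GIP1), -0.85 (SPS100), 1.86 (FIG2), -0.90 (CIT2), 0.85 (ARO3), -0.59 (TYR1), -0.65 (ARO4), -2.29 (ATF2) and -1.50 (HSP82). On day 4 they were -1.85 (PDA1), -0.97 (BMH1), -1.26 (CIT2), 1.355 (FIG2), 0.96 (STE6), -0.91 (STE4), -1.25 (MEP3), -0.50 (FTH1), 0.62 (ARO80), -0.63 (TYR1), -1.08 (ARO4), -2.42 (ATF2) and -1.22 (HSP82). In minimal medium they were -0.51 (CCA1), -1.86 (DNF1), -1.14 (TPS3) and -2.155 (ATF2).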

Other observations

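The values below were singled out after they had been seen, and no tests were made on them beyond those named.

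The copies of some genes moved apart within a strain. The nitrogen regulator DAL80 shifted toward its S. cerevisiae copy in W34/70 9.7, by 3.47 on the log2 scale from day 2 to day 4 and 5.44 from day 2 to minimal medium (limma). The day 4 call does not hold without day 2 replicate 3, day 4 replicate 2 or day 4 replicate 3, or without the 2 libraries that lack S. eubayanus VII counts, where 0 genes are called (439 at an unadjusted p under 0.05 with all libraries), and day 4 replicate 3 carries its level (60.4 CPM for the S. cerevisiae copy against 4.58 and 2.61). From day 2 to minimal medium in W34/70 9.7 the peroxiredoxin gene TSA2 shifted by -6.22 and RSB1 by -5.24, toward the S. eubayanus copy, and TMA10 by 4.73 toward the S. cerevisiae copy. In CBS1538 11.1, where the day 2 labels disagree, the balance of CDC4 shifted by 2.95 from day 2 to day 4. Its S. cerevisiae copy changed by 3.47 and its S. eubayanus copy was not called (0.57, adjusted p = 0.0596 by edgeR). That S. cerevisiae copy lies on chromosome VI, of which 3.67% of 109 features reached 1 CPM in CBS1538 11.1 on day 2. Whether the strain carries this copy is uncertain.

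Across the 5182 S. eubayanus features, which are not independent replicates, 746 were higher and 799 lower in both strains in minimal medium than on day 2 (326.0 and 324.8 if the calls were independent), and 119 were called in opposite directions. Against day 4, 675 were higher and 638 lower in both strains, and 109 were called in opposite directions.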
